A study of Mus musculus with 15 samples.

How the data were processed

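RNA was measured on Affymetrix mouse expression arrays in 15 samples, 3 from each of 5 cell lines. NMuMG is a non-tumorigenic mouse mammary gland epithelial line. E1KD is NMuMG with hnRNP E1, the RNA-binding protein encoded by Pcbp1, silenced. M1P was recovered from a mammary fat pad tumour of E1KD cells after 1 passage in mice, L1P from lung after 1 passage, and L2P from lung after a second passage started with L1P. Per the labels' protocols, all lines were grown in the same medium, RNA was extracted with Trizol and a column kit, and 100 ng of total RNA was amplified from the 3' end and labelled with biotin.

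The deposited values are log2 signals per probe set, 1 table of 45101 probe sets for all 15 arrays, and they were used as deposited. Per the submitters' processing notes, the authors used RMA, MAS5 and the Affymetrix Expression Console; versions are not given in the sources used here. The values ranged from 1.53 to 14.68 with an array median of 4.2, and no pair of arrays was identical. No detection calls were used, so a low signal was not separated from no signal, and a fold change against a signal near the floor is compressed. Arrays carry no read depth; the number of arrays, 3 per line, limits the precision.

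Probe sets were named from the platform's annotation table, with symbols brought up to date by Entrez identifier in a RefSeq gene table (GRCm38.p6), which matched 34741 probe sets and left 204 with the platform's symbol. Exactly 1 symbol was given to 34945 probe sets, several to 932 and none to 9160; 64 were controls. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. Probe sets without a single symbol stayed out of the comparisons of genes and were tested separately.

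A linear model with 1 coefficient per line was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, and moderated two-sided tests were made for 6 comparisons: E1KD with NMuMG; M1P, L1P and L2P with E1KD; L2P with L1P; and L1P with M1P. P-values were adjusted by Benjamini and Hochberg over the 18193 genes of a comparison, and genes with an adjusted p under 0.05 are said to have risen or fallen. Moderated F tests covered the 5 lines and the 4 silenced lines. The model had 10 residual and 2.98 prior degrees of freedom. All lines shared 1 estimate of spread, so unequal spread between lines affects every comparison. The labels do not say whether the 3 arrays of a line came from separate cultures, so the p-values measure spread between arrays that may be technical. Each line is 1 line, and the tests compare lines, not independently derived ones.

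The test was tried on 5 simulated data sets per comparison with the genes' own means and spread, each line's own scale of noise, and 200 of 18193 genes changed. At a log2 change of 1 it recovered 66.9% of changed genes for E1KD with NMuMG, 67.5% for M1P with E1KD, 63.6% for L1P with E1KD, 63.9% for L2P with E1KD, 66.6% for L2P with L1P and 68.1% for L1P with M1P. At a log2 change of 0.5 it recovered 9.3%, 19.4%, 10.7%, 13.4%, 11.6% and 15.8% in the same order, so genes with such changes would mostly not pass. False genes made up 1.1%, 23.8%, 0.2%, 1.2%, 2.2% and 23.3% of the calls in the same order. Noise was drawn separately for each gene, so these shares do not carry over to arrays that deviate in many genes together.

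Gene lists written by hand were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison, 186 tests in all, with camera at an estimated correlation and fry beside it. The 23 pathway lists were epithelial junctions and polarity; mammary keratins and basal or luminal markers; mesenchymal genes and EMT transcription factors; the TGF-beta pathway and its targets; hnRNP E1 translational targets with the ILEI and LIFR axis; poly(C)-binding and related hnRNP genes; collagens and matrix; matrix proteases and inhibitors; integrins and adhesion receptors; lung metastasis genes; mammary stem cell and tumour-initiating markers; proliferation; p53 targets and cell cycle inhibitors; interferon response; antigen presentation; cytokines and chemokines; hypoxia and glycolysis; cholesterol synthesis; oxidative stress (Nrf2) and glutathione; ER stress and the unfolded protein response; ErbB ligands and receptors; the Wnt pathway; and imprinted growth genes. The 8 cell type lists were fibroblast, endothelial, macrophage and leukocyte, alveolar and airway epithelium, adipocyte, skeletal muscle, erythrocyte and mammary secretory. Members that rose or fell were counted over all genes tested and adjusted over the list alone.

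Named genes followed a fixed rule. It took 9 fixed genes (Pcbp1, Dab2, Fam3c, Inhba, Lifr, Cdh1, Cdh2, Vim and Fn1). It took the 8 largest rises and 8 largest falls per comparison whose 3 arrays of one line all lay beyond those of the other. It took up to 2 of the largest rises and falls among the passing members of a list, and up to 5 genes per direction that moved the same way at both lung passages. The lists, this rule, the tests and the alternatives listed first below were chosen before the data were examined.

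Overlaps between comparisons that share the E1KD arrays were set beside 50 simulated data sets with unchanged lines and beside the overlap of independent lists. After the data were seen, 50 more were made in which the changes of the passaged lines, in units of each gene's SD, were moved to other genes of like mean signal. Counts were also compared with every other split of 3 against 3 arrays, and with 100 random regroupings for the F tests and overlaps. The alternatives chosen first were quantile normalization again, centring on the array median, 2 filters on dim genes, 3 other treatments of the probe sets of a gene, a variance model with trend and robust estimation, the replicate number as a block, only the lines compared in the model, and leaving out each array in turn. Chosen after seeing the data were the model without M1P arrays 1 and 2, the model without those and L2P array 1, the 75th percentile of each array as a covariate, and array weights. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.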

Results

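The 15 arrays give 1 log2 expression table for 5 related mouse mammary epithelial lines with 3 arrays each: the parental NMuMG line, the silenced line E1KD, the tumour line M1P and the lung lines L1P and L2P. Arrays of the same line correlated at 0.93 to 0.996 over all probe sets, controls included. Values after ± are the SD of a line's 3 arrays for a level and the standard error for a log2 difference, and adjusted p-values are from limma.

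Pcbp1, which encodes hnRNP E1, a protein that binds C-rich RNA and holds back translation of selected messages, was low in every silenced line. Its log2 signal was 12.68 ± 0.10 in NMuMG, 9.25 ± 0.22 in E1KD, 9.83 ± 0.36 in M1P, 8.49 ± 0.42 in L1P and 8.15 ± 0.18 in L2P (SD, n = 3). The 12 arrays of silenced lines lay between 7.95 and 10.09, and the NMuMG arrays between 12.57 and 12.76. All arrays matched their labels in this respect.

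**Figure D1:**
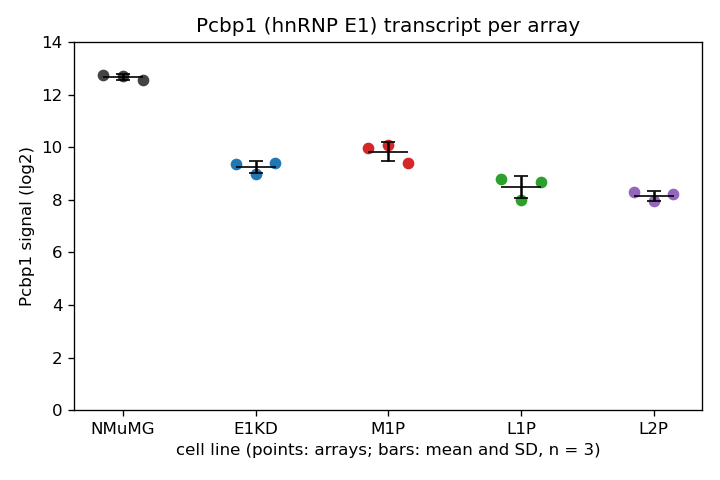
Log2 signal of Pcbp1 on each array (points) with the mean and SD of each line (black, n = 3), from NMuMG through the silenced and passaged lines. The NMuMG arrays lie at 12.57 to 12.76 and the arrays of the 4 silenced lines at 7.95 to 10.09.

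The lines were first compared as a whole. Of 18193 genes, 5786 (31.8%) differed among the 5 lines and 4978 (27.4%) among the 4 silenced lines by limma's F test. The first number was 8910 without M1P array 3. The second was 3291 without E1KD array 2, 2857 without M1P array 1, 8208 without M1P array 3 and 3125 without L1P array 3. L1P and L2P were the closest pair, with a mean distance of 47.9 between their arrays, against 38.3 within L1P and 54.7 within L2P. E1KD lay 60 from L1P, 69.7 from L2P and 86.2 from NMuMG. M1P was scattered: its own arrays were 107.2 apart on average, nearly as far as from E1KD at 112.2. M1P array 1 scored -136.4 and array 2 -57.9 on the first component, array 3 -6.1. On this component, with 56.7% of the variance, NMuMG lay at -40.5 to -12.2 and E1KD at 11.6 to 40.6, so it also set these lines apart. The second component set NMuMG, at 48.5 to 56.5, apart from E1KD, at 3.7 to 10.4, and from the passaged lines, all below 0.

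**Figure D2:**
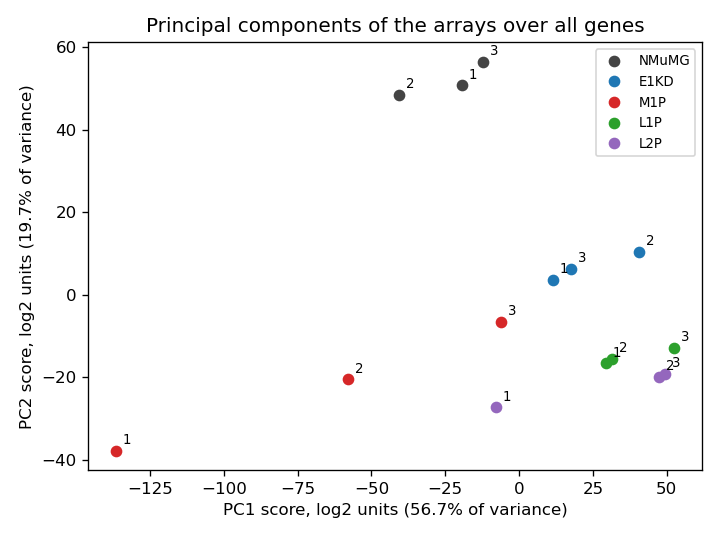
Scores of the 15 arrays on the first and second principal components over all genes (log2 units; numbers are the arrays of a line). M1P arrays 1 and 2 lie far to the left at -136.4 and -57.9, and M1P array 3 at -6.1.

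E1KD was set against NMuMG to ask what differs in mammary epithelial cells with hnRNP E1 silenced. The series holds no control vector line and no other line silenced directly from NMuMG. Effects of silencing therefore cannot be told from other differences between the lines. Pcbp1 fell 10.8-fold (log2 change -3.44 ± 0.22, n = 3 arrays per line, adjusted p = 3.89e-07). Fn1, the matrix protein fibronectin, rose 12-fold (3.59 ± 0.34, adjusted p = 1.85e-05) and Snai2, a repressor of epithelial genes, rose by 3.23 ± 0.45 log2 units. Cdh1, the epithelial E-cadherin, stayed at a log2 signal of 11.17 ± 0.19 against 11.14 ± 0.38 in NMuMG. In total 546 genes rose and 1181 fell, 332 and 516 of them at least 2-fold. The total of 1727 was 1138 without NMuMG array 1, 999 without E1KD array 2 and 3439 with only these lines in the model.

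Largest among the rises was Lhfp, a tetraspan membrane protein gene, which went from 2.46 to 9.20 (107-fold, adjusted p = 1.7e-09). It was followed by the glutamine transporter Slc38a1 (42.7-fold), the GTPase Rab32 (39.7-fold) and the small heat shock protein Hspb8 (38-fold). Then came the branched-chain aminotransferase Bcat1 (32.2-fold), Dynap (31.3-fold), the heparan sulfate sulfotransferase Hs6st2 (30.6-fold) and Tead2, a DNA-binding partner of Yap (28.9-fold). The peroxiredoxin Prdx4 fell 188-fold, from 10.38 to 2.83 (adjusted p = 3.61e-13). Eva1b fell 64.7-fold, Tm4sf1, a membrane protein of motile cells, 51.4-fold and the simple-epithelial keratin Krt7 43.9-fold. The galectin Lgals4 fell 41.1-fold, the chemokine scavenger Ackr3 28.4-fold, the apical transport protein Mal2 27.6-fold and the cadherin Cdh16 26.9-fold. Cdh2, the mesenchymal N-cadherin, rose 2.64-fold (adjusted p = 0.0163). This call ended on leaving out NMuMG array 1 (adjusted p = 0.058) or 3 (0.0582), or E1KD array 1 (0.0556) or 3 (0.0611), within a range of 0.000291 to 0.0611 over 19 alternatives. Inhba, the activin A subunit, rose 2.19-fold (adjusted p = 0.00611). Dab2 (0.49 ± 0.20, adjusted p = 0.177), Fam3c, which encodes ILEI (0.30 ± 0.16, 0.324), Lifr (0.12 ± 0.16, 0.743) and Vim (0.29 ± 0.11, 0.151) did not pass. Lifr was at 0.97 with its probe set of largest variance (adjusted p = 0.00855, in a range up to 0.99). Dab2 passed under 4 of 18 alternatives, with only these lines among them (adjusted p = 0.0296, range 0.0267 to 0.791), and Fam3c with array weights (0.0392, range up to 0.599). Dab2 and Fam3c are messages that hnRNP E1 holds back in translation, which arrays of RNA do not measure.

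Among the lists, mesenchymal genes and EMT transcription factors were shifted up by camera (adjusted p = 0.0222, median 0.18). Of 24 genes, Fn1, Snai2 and Cdh2 rose and 0 fell, also when adjusted over the list alone. By limma 8 had an unadjusted p under 0.05, 6 of them higher and 2 lower. Over the whole list 16 genes were higher and 8 lower. The list had an adjusted p = 0.959 with an estimated correlation, 0.0846 by fry and 0.0907 without NMuMG array 3; over 21 alternatives it ran from 0.0033 to 0.959. Of 29 junction and polarity genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone), among them the tight junction genes Marveld2 (-2.96) and Ocln (-1.69) and the polarity gene Crb3 (-1.35). Its camera adjusted p was 0.167. Of 19 keratins and mammary markers, 3 fell, Krt7, Krt20 (-2.35) and the mucin Muc1 (-2.03), and the luminal factor Foxa1 rose (2.59). The matrix lists lost the laminin chains Lamb3 (-3.09) and Lamb1 (-1.48), while the fibulin Fbln2 rose (2.07), leaving 23 of 26 not passed. Of 22 matrix proteases and inhibitors, Adam8 (-1.63), Timp1 (-1.36) and Timp2 (-1.04) fell. Integrin Itgb4, which anchors epithelia to the basement membrane, fell (-1.67), as did Cd82 (-1.31), and Vcam1 rose (2.17), out of 21 adhesion receptors.

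In the TGF-beta list 3 of 24 genes rose, led by Id3 (1.97) and Ltbp1 (1.18), and 4 fell, led by the co-receptor Tgfbr3 (-2.75) and the inhibitor Smad7 (-1.08). Of 11 genes of the hnRNP E1 target list, Inhba rose, and Socs3 (-1.09) and Ppp1r10 (-0.49) fell. In the list of 10 poly(C)-binding and related hnRNP genes only Pcbp1 fell; the list median was 0.23 and the mean -0.21, and camera gave an adjusted p of 0.7. The cytokine list lost 4 of 27 genes, with Il33 (-1.96) and Il18 (-1.58) the largest falls, and the interferon list 3 of 27, with Oasl1 (-1.54) and Isg20 (-1.11). The class I antigen genes H2-D1 (1.82) and H2-K1 (1.35) rose, and the other 11 of 13 genes did not pass. In hypoxia and glycolysis the phosphofructokinase Pfkp rose 28.8-fold and 3 of 23 genes fell, Pfkl (-0.99) and the glucose transporter Slc2a1 (-0.85) the most. In the Nrf2 and glutathione list 3 of 22 genes rose, led by Gsta3 (2.60) and Tkt (0.55), and 4 fell, led by Gsr (-0.82) and Gstp1 (-0.76). Among imprinted growth genes Igf2r rose (3.31) and Ndn fell (-1.96), out of 15.

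Smaller counts were found in the remaining lists. Lung metastasis genes had 2 rises, Vcam1 and Ltbp1, and 2 falls, Lxn (-2.02) and Tspan8 (-1.22), of 17. For stem cell markers there was 1 rise, Sox9 (1.06), of 20, and for proliferation 1 rise, Ccne1 (0.62), and 1 fall, E2f1 (-0.72), of 29. In the p53 list Eda2r (2.65) and Plk2 (0.86) rose and Gadd45b (-1.29) and Fas (-0.77) fell, of 22. Cholesterol synthesis had 3 falls of 20, Pmvk (-1.41), Fdps (-0.91) and Ebp (-0.80). In the ER stress list Xbp1 fell (-0.80), 1 of 21. In the ErbB list Nrg1 (1.13) and Dusp4 (1.02) rose, of 20, and in the Wnt list Fzd2 rose (1.11) and Wnt7b (-1.09) and Wnt7a (-0.50) fell, of 24. Among the cell type lists Aqp5 rose (2.05) and Sftpd fell (-0.65) in alveolar and airway epithelium, of 13. Flt1 rose (0.96) and Egfl7 fell (-0.93) among 12 endothelial genes, and Csn3 fell (-1.31) among 8 mammary secretory genes. In the fibroblast, macrophage and leukocyte, adipocyte, skeletal muscle and erythrocyte lists 0 members passed in limma, and 2, 2, 1, 0 and 0 had an unadjusted p under 0.05; fry gave these lists adjusted p-values of 0.658 to 0.779.

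M1P was set against E1KD to ask what differs in silenced cells recovered from a mammary tumour. Tm4sf1, lower in E1KD than in NMuMG, rose 120-fold (6.91 ± 0.18, n = 3, adjusted p = 6.62e-11), to 13.35 against 12.12 in NMuMG. Crip1, a LIM domain protein, rose 51.2-fold. The imprinted gene Peg3 fell 62.3-fold (-5.96 ± 0.64, adjusted p = 0.000164) and Xist, the RNA that silences an X chromosome, 46.4-fold. Pcbp1 itself was 9.83 ± 0.36 against 9.25 ± 0.22 and did not pass (0.58 ± 0.22, adjusted p = 0.0631). It passed without M1P array 3 (adjusted p = 0.0108), within a range over alternatives that reached 0.799 without M1P arrays 1 and 2.

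Other large rises were the Wnt ligand Wnt10a (29.2-fold), the chemokine Cxcl3 (24.4-fold), the kinase Mapk12 (24.3-fold), the casein Csn3 (15.8-fold), the connexin Gjb5 (13.1-fold) and Ly6e (12.7-fold). Klhl13 fell 37.4-fold, the creatine synthesis enzyme Gatm 31-fold, Bcat1 14.3-fold and the thrombin receptor F2r 13.1-fold. Leaving out M1P arrays 1 and 2, a setting chosen after seeing the data, leaves M1P as 1 array, whose spread is then taken from the other lines. In array 3 alone these 14 genes differed from E1KD by 2.37 (Cxcl3, against 4.61 with all arrays) to 6.80 log2 units (Tm4sf1). The rule that named them requires all 3 M1P arrays to lie beyond the E1KD arrays. Their direction in array 3 was thus fixed, and only the size is informative. Peg3 was at -4.32 against -5.96 and Wnt10a at 3.59 against 4.87. Cxcl3 had an adjusted p of 0.0978 with only M1P and E1KD in the model, the highest of its 18 alternatives, which began at 1.88e-08. Med13 (11.1-fold) and Atrx (10.8-fold) also fell, but had log2 changes of -1.97 and -0.98 and adjusted p-values of 0.134 and 0.656 without M1P arrays 1 and 2, the highest of ranges that began at 0.000295 and 0.00121. Atrx also missed the threshold without E1KD array 2 (adjusted p = 0.104) or 3 (0.052), or M1P array 1 (0.104) or 2 (0.0623). Fam3c fell 2.89-fold (adjusted p = 0.000164, and 0.0626 with only these lines in the model). Cdh2 fell 2.92-fold (adjusted p = 0.00898), and its adjusted p was 0.0538 without M1P arrays 1 and 2 and up to 0.245 with the 75th percentile as a covariate. Inhba (-0.57, adjusted p = 0.0751) and Fn1 (-0.97, 0.0518) did not pass and passed under some alternatives; without M1P array 3 Inhba had 0.0375, and without M1P array 2 Fn1 had 0.0374. Cdh1 (-0.49, adjusted p = 0.149) passed without M1P array 2 (0.0351), and Dab2 (0.22, 0.395) without M1P array 3 (0.0414). Vim (-0.09, adjusted p = 0.511) and Lifr (0.11, 0.606) did not pass, but with its probe set of largest variance Lifr was at -0.94 (adjusted p = 0.0102, in a range up to 0.913).

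Counts for M1P depended on the arrays used. With all 15 arrays 3221 genes rose and 1794 fell, 599 and 1264 of them at least 2-fold; without M1P arrays 1 and 2 the numbers were 412 and 397, and 679 of the 5015 genes kept their direction and call. With only M1P and E1KD in the model 67 genes passed. The total was 3136 without E1KD array 1, 1106 without E1KD array 2, 2396 without E1KD array 3, 2021 without M1P array 1 and 8510 without M1P array 3. The 2-fold total of 1863 was 583 without E1KD array 2, 1154 without E1KD array 3, 634 without M1P array 1 and 3462 without M1P array 3. The median change of all genes was 0.20 in M1P, and 0.10 after quantile normalization, so list medians are also given relative to it. On data simulated with this spread, 23.8% of the calls were false.

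**Figure D3:**
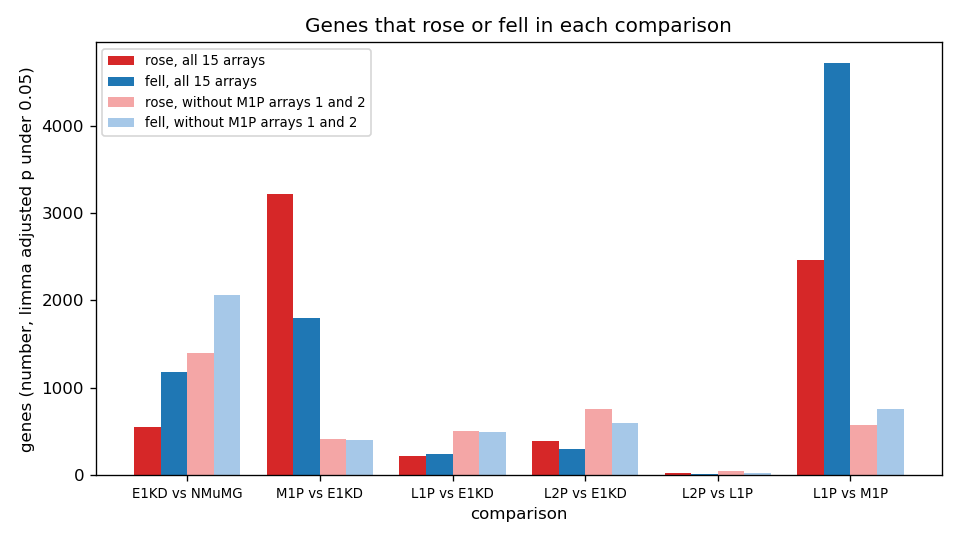
Number of genes that rose or fell at a limma adjusted p under 0.05 in each comparison, with all 15 arrays (dark bars) and without M1P arrays 1 and 2 (light bars). M1P with E1KD goes from 3221 rises and 1794 falls to 412 and 397, and E1KD with NMuMG from 546 and 1181 to 1402 and 2061.

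Of the 31 lists, proliferation was shifted in M1P with E1KD, downward (median -0.36, or -0.56 relative to all genes, camera adjusted p = 0.00593). It had an adjusted p = 0.822 with an estimated correlation, 0.17 without M1P arrays 1 and 2, and 0.00225 to 0.822 over 21 alternatives. Of 29 genes, 9 fell, led by Mki67 (-3.09) and Top2a (-2.84), which cycling cells express, and 3 rose, led by E2f1 (0.87) and Mcm5 (0.59); the counts adjusted over the list alone were the same 9 and 3. In M1P array 3 alone Mki67 was at -0.87 (adjusted p = 0.587) and Top2a at -0.78 (0.488). Interferon genes rose in 9 of 27 cases, Oasl1 (2.52) and the restriction factor Bst2 (1.12) the most, and Ifit2 fell (-2.04). In antigen presentation 5 of 13 rose, led by H2-M3 (2.19) and H2-D1 (1.59). In the Wnt list 7 of 24 rose, led by Wnt10a and the receptor Fzd1 (1.94), and Lrp6 fell (-1.83). In the matrix list 5 of 26 rose, led by Col6a1 (2.78) and Col6a2 (1.76). Epithelial junction genes had 6 rises, led by Marveld2 (1.52) and Jup (1.12), and 2 falls, Tjp1 (-1.55) and Dsp (-1.26), of 29. Over all genes 3221 of 18193 rose and 1794 fell, so such counts alone do not set a list apart. Relative to all genes the medians of the interferon, antigen, Wnt, matrix and junction lists were 0.13, 0.19, 0.10, 0.12 and 0.08. The EMT transcription factors Zeb1 (-1.87) and Zeb2 (-2.13) fell, with log2 changes of -0.53 and -0.33 without M1P arrays 1 and 2. In cholesterol synthesis 5 of 20 fell, led by Idi1 (-2.19) and Hsd17b7 (-1.59), and Mvk rose (0.84); the list median was 0.08, or -0.12 relative to all genes, the mean -0.26 and the camera direction down (adjusted p = 0.23, and 0.000973 without M1P arrays 1 and 2).

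Markers of other cell types were mostly higher in M1P than in E1KD, as were most genes. This held for 12 of 12 endothelial, 13 of 13 alveolar and airway, 12 of 13 macrophage and leukocyte, 10 of 12 fibroblast, 8 of 8 skeletal muscle and 7 of 8 mammary secretory genes. Relative to all genes the medians were 0.14, 0.18, 0.11, 0, 0.10 and 0.21. Of these, 2, 4, 1, 1, 2 and 2 genes rose in limma, Csn3, Foxj1 (1.99) and Col1a2 (1.09) the most, and no gene of these 6 lists fell, also at an unadjusted p under 0.05. Of 8 adipocyte genes Fabp4 fell (-0.87) and none rose, with a list median of -0.16 relative to all genes. All 4 erythrocyte genes were higher, with 0 passing in limma and 0 at an unadjusted p under 0.05. Camera gave these 8 lists adjusted p-values of 0.23 to 0.645, and 0.824 for each with an estimated correlation. By fry the endothelial (adjusted p = 0.0493), skeletal muscle (0.0493) and mammary secretory lists (0.011) passed, the lowest of ranges that reached 0.824, 0.955 and 0.824.

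L1P was set against E1KD to ask what changed in silenced cells that had colonised the lung once. Crip1 rose 80.1-fold (6.32 ± 0.16, n = 3, adjusted p = 4.88e-11), and the growth factor receptor Erbb3 rose 53.2-fold (5.73 ± 0.39, adjusted p = 1.92e-06), from 4.70 to 10.43. Xist fell 66.9-fold (-6.06 ± 0.35) and Peg3 58.7-fold (-5.88 ± 0.64). Pcbp1 was 8.49 ± 0.42 against 9.25 ± 0.22 and did not pass (adjusted p = 0.114). In total 217 genes rose and 235 fell, 133 and 145 of them at least 2-fold. The total of 452 was 298, 292 and 294 without E1KD arrays 1, 2 and 3, and 272, 274 and 286 without L1P arrays 1, 2 and 3. With only these lines in the model it was 1195.

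Further rises were Tm4sf1 (26.7-fold), the drug efflux pump Abcb1b (23.8-fold), Mapk12 (22.8-fold), the synuclein Sncg (15.4-fold), the RNA export factor Nxf3 (8.69-fold) and the leukocyte receptor Ly9 (8.62-fold). Klhl13 fell 42.4-fold, Gatm 34.7-fold, Bcat1 31.2-fold, the RNA-binding protein Khdrbs3 27.1-fold, Elmod1 17.1-fold and the microtubule linker Hook1 16.9-fold. Fn1, higher in E1KD than in NMuMG, fell 3.98-fold (adjusted p = 0.00532), to 7.59 ± 0.49, still above its 6 ± 0.35 in NMuMG. Dab2 (-0.59, adjusted p = 0.231), Fam3c (-0.36, 0.481), Inhba (-0.64, 0.251), Lifr (-0.34, 0.51), Cdh1 (-0.46, 0.652), Cdh2 (-0.47, 0.821) and Vim (0.13, 0.917) did not pass. Pcbp1 passed under 3 of 19 alternatives (adjusted p = 0.0155 to 0.443), Dab2 under 4 of 18 (0.0281 to 0.754), Fam3c under 1 of 19 (0.0273 to 1) and Lifr under 2 of 18 (0.016 to 0.855).

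Cholesterol synthesis was the most shifted list in L1P (median -0.73, camera adjusted p = 3.76e-12, n = 3). It had an adjusted p = 0.151 with an estimated correlation, the highest of 21 alternatives that began at 2.73e-15. Each of the 20 genes had a lower mean than in E1KD. Over all genes tested 5 fell, led by Tm7sf2 (-1.58) and Mvd (-1.27), with Nsdhl (-1.15), Fdps (-1.08) and Sqle (-0.82); 11 fell when adjusted over the list alone. Matrix proteases and inhibitors were shifted up (median 0.05, mean 0.27, camera adjusted p = 0.0276), with the membrane protease Adam8 (2.25) and the stromelysin Mmp10 (1.24) rising, 2 of 22, and 6 adjusted over the list alone. That list had an adjusted p = 0.774 with an estimated correlation and 0.0544 without L1P array 1, in a range of 0.00204 to 0.774. ER stress genes were shifted up (median 0.18, adjusted p = 0.0353), and Xbp1, a transcription factor of the unfolded protein response, rose (1.00), 1 of 21 by either adjustment. This list had an adjusted p = 0.774 with an estimated correlation. It missed the threshold without E1KD array 1 (adjusted p = 0.0606) or 2 (0.114) or L1P array 2 (0.346), in a range of 0.00308 to 0.774. In other lists the secreted protein Thbs1 (-2.84) and Ccn2 (-1.74) fell, 2 of 24 TGF-beta genes, and S100a4 (-2.05) fell beside Fn1 in the mesenchymal list. Marveld2 rose (1.55), 1 of 29 junction genes, Muc1 fell (-2.54), and the stem cell markers Procr rose (2.01) and Abcg2 fell (-2.52). The lymphatic growth factor Vegfc fell (-2.58) and Il33 rose (1.76), both of the cytokine list.

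L2P was set against E1KD to ask what had changed after 2 rounds of lung colonisation. Tm4sf1 rose 108-fold (6.76 ± 0.18, n = 3, adjusted p = 5.34e-11), Cxcl3, which attracts neutrophils, 93.6-fold, Crip1 86.6-fold and Erbb3 62-fold. Peg3 fell 319-fold, from 11.17 to 2.85 (adjusted p = 4.3e-06), and the growth factor homolog Fgf13 fell 182-fold, from 9.98 to 2.47. Pcbp1 was 8.15 ± 0.18, 2.14-fold below E1KD (adjusted p = 0.0113); this call ended without E1KD array 1 (adjusted p = 0.053) or 3 (0.059) or L2P array 2 (0.0651), in a range of 0.000253 to 0.0651. In total 389 genes rose and 298 fell, 223 and 175 of them at least 2-fold. The total of 687 was 424 without E1KD array 2, 453 without E1KD array 3 and 446 without L2P array 2. With only these lines in the model it was 867.

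The other large rises were Sncg (25.4-fold), Mapk12 (19.6-fold), Abcb1b (18.7-fold) and the bicarbonate transporter Slc4a5 (9.84-fold). Xist fell 62.4-fold, Klhl13 38.6-fold, Bcat1 35.3-fold, Gatm 31.4-fold, Khdrbs3 30.7-fold and Hook1 21.3-fold. Fn1 was 8.37 ± 0.44 (-1.22, adjusted p = 0.0773) and Fam3c 9.55 ± 0.05 (-0.58, 0.0758); neither passed. Fam3c passed under 8 of 19 alternatives, among them quantile normalization (adjusted p = 0.0361), centring on the median (0.0442) and only these lines (0.0452), in a range of 0.00146 to 0.953. Fn1 passed under 6 of 19, among them the mean of its probe sets (adjusted p = 0.00117), in a range up to 0.305. Nor did the others pass, Dab2 (-0.61, adjusted p = 0.162), Inhba (-0.63, 0.217), Cdh1 (-0.69, 0.231), Cdh2 (-0.83, 0.296), Vim (0.16, 0.774) and Lifr (-0.16, 0.936). Dab2 passed under 4 of 18 alternatives (adjusted p = 0.0174 to 0.696), Cdh1 under 2 of 19 (0.0175 to 0.588), Cdh2 under 3 of 19 (0.0284 to 0.601) and Lifr under 1 of 18 (0.0158 to 1).

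Cholesterol synthesis was again the most shifted list (median -1.14, camera adjusted p = 9.9e-19), and it passed with an estimated correlation (adjusted p = 0.0372). Of its 20 genes 10 fell, led by Mvd (-1.43) and Hsd17b7 (-1.36), and 16 fell when adjusted over the list alone. Nrf2 and glutathione genes were shifted up (median 0.30, adjusted p = 0.0107), with Gstp1 rising (0.84), 1 of 22, and 7 adjusted over the list alone. The list had an adjusted p = 0.873 with an estimated correlation and 0.072 without L2P array 3, in a range of 0.000624 to 0.873. Poly(C)-binding and related hnRNP genes were shifted down (median -0.23, adjusted p = 0.0208), with Pcbp1 the only member of 10 to fall by either adjustment. That list had an adjusted p = 0.873 with an estimated correlation. It missed the threshold without E1KD array 3 (adjusted p = 0.065) or L2P array 1 (0.0538) or 3 (0.0581), in a range of 0.00903 to 0.873. Class I antigen genes rose, H2-D1 (2.02) and H2-K1 (1.83) the most, 3 of 13. The interferon factors Irf9 (1.41) and Ifih1 (1.38) rose, 2 of 27. Proteases had 4 rises of 22, Adam8 (1.99) and Mmp10 (1.15) first. Marveld2 rose (2.55), the EMT factor Twist2 rose (1.71), and Ncam1 (-1.72) and S100a4 (-1.66) fell. Lyz1 rose (2.27), 1 of 13 macrophage and leukocyte genes, and Csn3 rose (2.07).

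**Figure D4:**
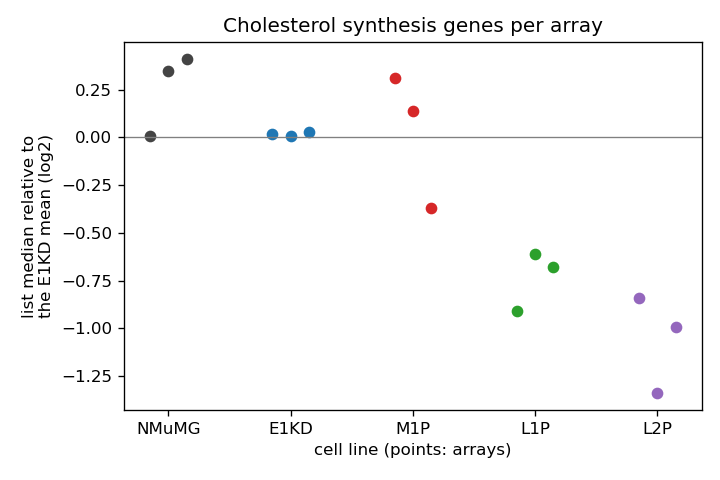
Median log2 signal of the 20 cholesterol synthesis genes on each array relative to the E1KD mean (points; lines along the x axis). L1P arrays lie at -0.91 to -0.61 and L2P arrays at -1.34 to -0.84, and E1KD arrays at 0.01 to 0.03. M1P arrays lie at -0.37 to 0.31 and NMuMG arrays at 0.01 to 0.41.

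L2P was set against L1P to ask what the second lung passage added. Cxcl3 rose 93.2-fold (6.54 ± 0.65, n = 3, adjusted p = 0.000331), from 2.50 to 9.04, and its neighbour in function Cxcl2 4.17-fold. Fgf13 fell 146-fold (-7.19 ± 0.23, adjusted p = 2.73e-09), from 9.66 to 2.47. With all arrays few other genes passed: 17 rose and 9 fell, each at least 2-fold, and 414 had an unadjusted p under 0.05. The total of 26 was 18 without L2P array 2, 34 without L2P array 1 and 36 with only these lines in the model. Other settings, given below, moved it further. Pcbp1 was 8.15 ± 0.18 against 8.49 ± 0.42 (-0.34 ± 0.22, adjusted p = 1).

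Slc4a5 rose 9.66-fold, Epb41l4a, a membrane skeleton protein, 7.6-fold, the leukocyte integrin Itgb2 7-fold, the purine oxidase Xdh 5.1-fold, the adaptor Grap 4.94-fold and Pstpip1 4.41-fold. The adhesion protein Flrt2 fell 4.64-fold, Slc18b1 4.53-fold, Cyp2j6 4.22-fold, Magea5 3.81-fold, the sulfotransferase Chst15 3.36-fold, the lipid droplet protein Bscl2 2.97-fold and Tm4sf4 2.48-fold. Some of these calls missed the threshold with 1 array fewer, at similar log2 changes. Xdh missed the threshold without L1P array 1 (adjusted p = 0.0648) or 3 (0.0571) or L2P array 2 (0.0695) or 3 (0.0656). Cyp2j6 missed it without L1P array 2 (0.0518) or L2P array 2 (0.0611), and Chst15 without L1P array 1 (0.0565) or 3 (0.0696). Tm4sf4 missed it without L1P array 1 (0.0526) or 2 (0.063) or L2P array 2 (0.0733) or 3 (0.0656). Bscl2 missed it on leaving out any array, L1P 1 (0.151), 2 (0.187) or 3 (0.174) or L2P 1 (0.103), 2 (0.22) or 3 (0.113). None of the other fixed genes passed, from Cdh2 (-0.36 ± 0.33) to Fn1 (0.78 ± 0.34), each with an adjusted p of 1.

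Small shifts in the same direction made up the list results. Cholesterol synthesis was lower again (median -0.21, camera adjusted p = 1.92e-05), and 19 of its 20 genes had a lower mean in L2P. Limma passed 0 of its members, also when adjusted over the list alone, and 1 had an unadjusted p under 0.05; the list had an adjusted p = 0.944 with an estimated correlation and 0.994 by fry. Hypoxia and glycolysis was higher (median 0.14, adjusted p = 0.000708), with 0 members passing in limma by either adjustment, 1 at an unadjusted p under 0.05, an adjusted p = 0.944 with an estimated correlation and 0.994 by fry. Over 21 alternatives their ranges were 2.6e-08 to 0.994 and 9.17e-05 to 0.994.

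Genes that moved the same way at both lung passages were sought as markers of progression, and 4 were found. Tm4sf1 rose by 4.74 and then 2.02 log2 units (adjusted p = 2.54e-09 and 7.73e-05). The protease inhibitor Wfdc15a rose by 1.38 and 1.44 (0.000425 and 0.00148), and the neutrophil antigen Cd177 by 0.66 and 1.38 (0.00933 and 8.32e-05). Chst15 fell, -1.24 and then -1.75 (0.0171 and 0.0086). The rises were not particular to the lung lines, since Tm4sf1, Cd177 and Wfdc15a also rose in M1P with E1KD. Tm4sf1 stood at 13.35 in M1P and 12.12 in NMuMG, against 11.18 in L1P and 13.2 in L2P. Cd177 stood at 4.17 in M1P, between 3.45 in L1P and 4.83 in L2P. Wfdc15a was lower in M1P (4.92) than in L1P (5.76). Chst15 went from 7.77 in E1KD to 4.79 in L2P, toward its 4.5 in NMuMG. Independent lists would share 0.3 genes, and 50 simulated data sets with unchanged lines gave a mean of 0. Unchanged lines have few calls to share, so that 0 cannot weigh an overlap among real changes. Without L2P array 1 the number of genes moving alike was 7. Other settings, given below, moved this number in both directions.

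L1P was set against M1P to ask how lines recovered from lung and from mammary tumour differ after 1 passage. Nxf3 was 19.7-fold higher in L1P (4.30 ± 0.49, n = 3, adjusted p = 0.00019) and Abcb1b 16.9-fold. Ly6e was 38-fold lower (-5.25 ± 0.37, adjusted p = 5.42e-06) and the defensin Defb41 21.9-fold. Pcbp1 was 2.52-fold lower in L1P (adjusted p = 0.00177); without M1P arrays 1 and 2 the log2 difference was -0.92 and the adjusted p 0.0633, in a range of 0.00024 to 0.0706. The median change of all genes was -0.25, and -0.10 after quantile normalization. With all arrays 2466 genes rose and 4720 fell, 1818 and 750 of them at least 2-fold. Without M1P arrays 1 and 2, 577 rose and 750 fell, 1166 of the 7186 genes kept their direction and call, and with only these lines in the model 288 passed. The total was 3263 without M1P array 1, and 4591, 4528 and 2489 without L1P arrays 1, 2 and 3. The 2-fold total of 2568 was 999 without M1P array 1 and 1193 without L1P array 3. On data simulated with this spread, 23.3% of the calls were false, a share that does not carry over to the real calls. Its noise was drawn separately for each gene.

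Lower in L1P were also Cxcl3 (24.3-fold), the cathepsin Ctsh (13.2-fold), Gnb4 (12.7-fold), Scara3 (12.7-fold), the homeobox gene Irx3 (11.8-fold) and the retinol transporter Stra6 (11.1-fold). Set against M1P array 3 alone, which has no spread of its own, these 8 largest falls were lower in L1P by 2.14 (Scara3, against 3.67 with all arrays) to 4.76 (Defb41). The rule that named the largest falls and rises requires the 3 arrays of each line to lie apart. Their direction against array 3 was thus fixed, and only the size is informative. Cxcl3 was at -2.37 against -4.60 and Stra6 at -2.37 against -3.48; with only these lines in the model Cxcl3 had an adjusted p of 0.0629 and Scara3 0.0517. Among the largest rises Mycbp2 (11.5-fold) was 2.45 above M1P array 3, Nxf3 4.14 and Abcb1b 3.99. Taok1 (13.9-fold), Med13 (13.5-fold), the collagenase Mmp13 (12.3-fold), Ktn1 (11.9-fold) and Dmxl2 (11.6-fold) were 1.88, 2.25, 2.09, 1.56 and 2.41 above it and missed the threshold, with adjusted p-values of 0.175, 0.0733, 0.109, 0.187 and 0.0641; over all alternatives these reached 0.239, 0.106, 0.167, 0.308 and 0.0925. Fam3c was 2.25-fold higher in L1P (adjusted p = 0.000735, and 0.0536 with only these lines in the model). Dab2 (-0.81, adjusted p = 0.0126), Cdh2 (1.08, 0.025), Fn1 (-1.03, 0.0337) and Lifr (-0.45, 0.0424) passed. Without M1P arrays 1 and 2 they were at -0.31, 0.80, -0.42 and -0.46 with 0.374, 0.168, 0.596 and 0.24, and over all alternatives the adjusted p reached 0.374, 0.849, 0.648 and 0.715.

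These calls also missed the threshold with 1 array fewer. Dab2 missed the threshold without L1P array 3 (adjusted p = 0.0576). Cdh2 missed it without M1P array 1 (0.0955) or L1P array 1 (0.073) or 3 (0.101). Fn1 missed it without M1P array 1 (0.101) or 2 (0.098) or L1P array 2 (0.108) or 3 (0.104). Lifr missed it without M1P array 1 (0.0656), 2 (0.0932) or 3 (0.0576) or L1P array 1 (0.108), 2 (0.0578) or 3 (0.112). Inhba (-0.08, adjusted p = 0.788), Cdh1 (0.03, 0.926) and Vim (0.22, 0.12) did not pass.

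Proliferation was the list shifted between L1P and M1P, higher in L1P (median 0.34, or 0.58 relative to all genes, camera adjusted p = 0.00788). It had an adjusted p = 0.886 with an estimated correlation and 0.148 without M1P arrays 1 and 2, in a range of 0.00248 to 0.886. Mki67 (3.51) and Top2a (2.81) led 8 rises, and Cenpa (-0.86) and E2f1 (-0.83) led 3 falls, of 29, also when adjusted over the list alone. In cholesterol synthesis 11 of 20 genes fell (13 fell and 1 rose adjusted over the list alone), led by Mvk (-1.71) and Tm7sf2 (-1.67); its median was -0.71, or -0.47 relative to all genes, and its camera adjusted p 0.241. Of 26 matrix genes 7 fell, led by Col6a1 (-3.12) and Col6a2 (-1.63), and of 24 Wnt genes 8 fell, led by Wnt10a (-2.59) and Wnt4 (-2.45). The milk protein Csn3 fell (-2.32), the EMT gene S100a4 fell (-2.37), and Erbb3 rose (3.01). Interferon genes fell in 8 of 27 cases, Oasl1 (-2.66) and Isg20 (-0.98) the most, and the ciliary factor Foxj1 (-2.66) was among 6 falls of 13 alveolar and airway genes. Over all genes 4720 of 18193 fell and 2466 rose, so such counts alone do not set a list apart. Relative to all genes the medians of the matrix, Wnt, interferon and alveolar lists were -0.12, -0.15, -0.04 and -0.21. Set against M1P array 3 alone, Csn3, S100a4, Erbb3, Oasl1 and Foxj1 were at -2.23, -2.20, 4.10, -2.15 and -1.56.

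Markers of other cell types were mostly lower in L1P than in M1P, as were most genes. This held for 12 of 12 fibroblast, 10 of 12 endothelial, 13 of 13 alveolar and airway, 8 of 8 skeletal muscle, 4 of 4 erythrocyte, 8 of 8 mammary secretory, 9 of 13 macrophage and leukocyte and 7 of 8 adipocyte genes. In limma 5, 2, 6, 1, 0, 3, 3 and 0 of them fell, and 7, 4, 8, 1, 2, 4, 3 and 1 at an unadjusted p under 0.05; 1 macrophage and leukocyte gene rose. Relative to all genes the medians ran from -0.21 in the alveolar to 0.18 in the adipocyte list. Fry passed the first 6 lists (adjusted p = 0.0309, 0.036, 0.00796, 0.0309, 0.0112 and 0.00788), the lowest of ranges that reached 0.95. Camera gave all 8 adjusted p-values of 0.126 to 0.974.

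The passaged lines were compared for changes from E1KD that they share. Of all genes, 176 moved the same way in M1P, L1P and L2P, 109 up and 67 down. Crip1 went from 5.31 in E1KD to 10.99, 11.64 and 11.75 in M1P, L1P and L2P. Peg3 went from 11.17 to 5.21, 5.30 and 2.85, and Xist from 10 to 4.46, 3.93 and 4.03. L1P and L2P shared 395 genes, 203 up and 192 down, M1P and L1P 190, and M1P and L2P 304. Independent lists would share 1.2, 8.5, 61.6 and 98.3 genes in the same order. Simulated unchanged lines shared a mean of 0, 0, 0 and 0.02, but have few calls to share and cannot weigh overlaps among real changes. When real changes were moved to other genes in 50 data sets, a simulation chosen after seeing the data, sharing the E1KD arrays gave a mean of 36.4, 106.8, 313.6 and 409.5 genes. The last 2 exceed the real 190 and 304, but independent lists would also share more in these data sets (47.7, 209.8 and 279.2 for the last 3). The raw numbers therefore cannot decide whether overlaps of M1P with the lung lines go beyond the shared controls. Relative to independent lists the overlaps were 2.24, 1.49 and 1.47 times as many, against 46.5, 3.08 and 3.09 in the data. Such a ratio depends on how many genes pass, which differed between these data sets and the real data. For M1P with the lung lines the ratios therefore cannot decide it either.

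Single arrays moved these overlaps. The 176 genes were 94 without E1KD array 2 and 117 without L1P array 2. M1P and L1P shared 100 without E1KD array 2 and 125 without L1P array 2, and M1P and L2P shared 130 and 196 without E1KD arrays 2 and 3. L1P and L2P shared 256, 245 and 253 without E1KD arrays 1, 2 and 3, and 240, 249 and 258 without L1P arrays 1, 2 and 3. Without M1P arrays 1 and 2, 185 genes moved together in the passaged lines, and 106 of the 176 were among them, Crip1, Tm4sf1, Peg3 and Xist included.

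**Figure D5:**
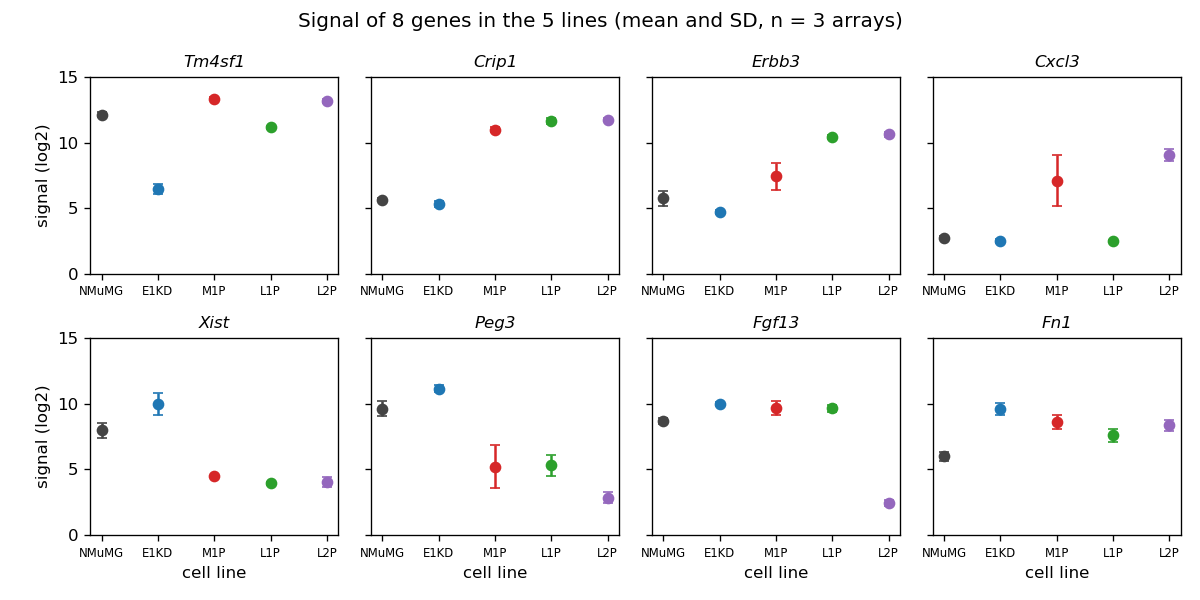
Log2 signal of Tm4sf1, Crip1, Erbb3, Cxcl3, Xist, Peg3, Fgf13 and Fn1 in the 5 lines (points are means, bars the SD of 3 arrays). Crip1 stands at 5.31 in E1KD and 11.75 in L2P, and Fgf13 at 9.66 in L1P and 2.47 in L2P.

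Some genes changed in E1KD moved back toward their NMuMG level in the passaged lines. Of the 1727 genes changed in E1KD, 771 moved back in M1P, 131 in L1P and 174 in L2P, and 95, 84 and 105 moved further. The M1P number depended on its arrays: without M1P arrays 1 and 2, 197 of the 771 passed the same way, while 770 had the same direction in array 3, which is part of the M1P mean. Independent lists would give 262.9, 21.1 and 34.2 for the first and 213.1, 21.8 and 31 for the second; these comparisons share the E1KD arrays with opposite sign. Simulated lines unchanged by passage gave a mean of 0.02, 0 and 0.06 undone and 0 further, and at most 1, but have few calls to share. With real changes moved to other genes and the E1KD arrays shared, the means were 912.7, 181.2 and 222.8 undone. For genes that moved further they were 519.9, 109.5 and 129, and all these lie above the real numbers. Independent lists would also share more there (628.5, 97 and 126.8 undone, and 494, 103 and 120.4 further). The raw numbers therefore cannot decide whether either goes beyond the shared controls. Relative to independent lists the means were 1.45, 1.87 and 1.76 times as many undone, against 2.93, 6.21 and 5.09 in the data. For genes that moved further they were 1.05, 1.06 and 1.07 times, against 0.45, 3.85 and 3.39. These ratios also depend on how many genes pass, which differed from the real data, so they cannot decide it either. Tm4sf1 fell to 6.44 and returned to 11.18 in L1P and 13.20 in L2P. Gatm and Bcat1, up from 2.56 and 2.44 to 7.41 and 7.45, returned to 2.30 and 2.49 in L1P. F2r stood at 10.54 in NMuMG, 6.17 in E1KD and 2.21 in L1P.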

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

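The tests of a shared factor and of RNA breakdown in M1P, of a chromosome 14 gain carried to L2P, of the share of higher genes in each part of chromosome 14 and of a further cholesterol fall, and the arrays of other lines and the separate E1KD arrays in the test of M1P array 3, were chosen only after the result was seen; the other tests were written down first.

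The change from E1KD differed between L1P and M1P for 6 of the 9 fixed genes, which is the test of L1P with M1P itself. The log2 differences were -1.33 for Pcbp1, -0.81 for Dab2, 1.17 for Fam3c, -0.45 for Lifr, 1.08 for Cdh2 and -1.03 for Fn1. The proliferation list differed by a median of 0.34 (camera adjusted p = 0.00788, and adjusted p = 0.886 with an estimated correlation). Set against M1P array 3 alone the 6 genes were at -0.92, -0.31, 1.04, -0.46, 0.80 and -0.42. That 1 array has no spread of its own, so calls lost there do not show that the differences were absent. With only these lines in the model Fam3c missed the threshold (limma adjusted p = 0.0536).

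Expressed genes of whole chromosomes also differed between L1P and M1P by camera, relative to the median of all genes. The medians were 0.39 for chromosome 1, -0.37 for 5, -0.38 for 7, 0.56 for 13, 0.8 for 14, -0.36 for 17, 0.6 for 18, -0.43 for 19 and 0.69 for X. With an estimated correlation chromosome 14 had an adjusted p of 0.0375 and each of the others 0.665. Without M1P arrays 1 and 2 and L2P array 1 the medians of chromosomes 1, 13, 18 and X were 0.08, 0.09, 0.16 and 0.02 and did not pass. Those of 5, 7, 14, 17 and 19 were -0.28, -0.26, 0.65, -0.14 and -0.32 and passed, but with an estimated correlation only chromosome 14 did, at an adjusted p of 0.0185 against 0.239, 0.759, 0.873 and 0.239 for 5, 7, 17 and 19.

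Probe sets without a single gene name carried signal that the comparisons of genes did not use. Of 10092 such probe sets, 258 changed between E1KD and NMuMG, 1162 between M1P and E1KD, 75 between L1P and E1KD, 105 between L2P and E1KD, 2 between L2P and L1P and 2161 between L1P and M1P.

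The first pattern weighed was the large number of genes apart between M1P and E1KD. It was 5015 with all arrays, 2021 without M1P array 1, 4960 without array 2 and 8510 without array 3. RNA broken down from its 5' end was argued against for the Gapdh and beta-actin controls only, which cannot exclude it for other transcripts. Their difference between 3' and 5' probes was 0.46 (SD 0.02, n = 2) in M1P arrays 1 and 2 and 0.59 (SD 0.07, n = 13) in the others. The log2 signal of the poly-A spike controls was 8.73, 8.09 and 9.22 on M1P arrays 1, 2 and 3. It was 7.88 to 8.55 in NMuMG, 7.18 to 7.70 in E1KD, 7.15 to 7.21 in L1P and 6.35 to 7.61 in L2P, and was not tested as a cause. A factor of array or culture shared with other lines is a candidate explanation. The deviation of M1P arrays 1 and 2 from array 3 correlated at 0.77 over genes with that of L2P array 1 from L2P arrays 2 and 3. A change of the M1P line stays open: of 3509 genes 2-fold apart in arrays 1 and 2, 3005 (85.6%; 1096 of 1169 higher and 1909 of 2340 lower) differed the same way in array 3, and 73.8 to 93.2% with separate E1KD arrays in the 2 differences. Of the other lines, L2P array 1 (89.8%) and NMuMG arrays 2 (88.2%), 1 (82.8%) and 3 (72.8%) agreed about as often, and the L1P arrays (57.3, 57.2 and 30%) and L2P arrays 2 and 3 (37.2 and 37.4%) less.

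The second pattern was the rise of chromosome 14 genes in both lung lines, by a median of 0.58 in L1P (camera adjusted p = 3.55e-39, and adjusted p = 0.000575 with an estimated correlation) and 0.56 in L2P. A trend in array quality was argued against, since the L1P median was 0.55 with the 75th percentile as a covariate, and so were a few strongly changed genes, since 93.9% of 263 genes lay above the median of all genes. A rise confined to one part was argued against: in each of 3 equal parts at least 90.9% of genes lay above the median of all genes in both lung lines, though the lowest of the L1P medians of 0.39, 0.63 and 0.72 leaves open a smaller rise there. A copy gain already present in L1P and kept in L2P is a candidate explanation, with a median of -0.02 between these lines and 0.58 the log2 ratio of 3 copies to 2. DNA was not measured.

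The third pattern was the lower cholesterol synthesis in the lung lines. Relative to the E1KD mean the list stood at 0.31, 0.14 and -0.37 on M1P arrays 1, 2 and 3, and at 0.01 to 0.41 in NMuMG. M1P array 3 thus shared the direction of the fall, to a smaller extent. A trend in array quality was argued against by a list median of -1.13 in L2P with the covariate, and shifts of whole chromosomes by -1.02 after each gene's chromosome median was taken off. Whether the fall went on in the second lung passage stays open: 95% of the genes (19 of 20) were lower in L2P, which only restates the difference, 0 of them passed in limma and 1 had an unadjusted p under 0.05. The list's adjusted p was 1.92e-05 by camera, 0.944 with an estimated correlation and 0.994 by fry, and L2P array 1 (-0.84) lay above L1P array 1 (-0.91). Medium is the same for all lines per the labels' protocols, and the state of the cultures at harvest stays open.

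The splits of 3 against 3 arrays are too few to judge a count, with 10 splits and a share never under 0.1. Only 1 of 10 splits, the real one, reached the real count in each comparison. The real counts and, in brackets, those at least 2-fold were 1727 (848) for E1KD with NMuMG, 5015 (1863) for M1P with E1KD, 452 (278) for L1P with E1KD and 687 (398) for L2P with E1KD. For these 4 the highest other split gave 0, as it did for L2P with L1P at 26 (26); for L1P with M1P at 7186 (2568) it gave 1.

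Of 100 regroupings, 1, the real one, reached 5786 genes among the 5 lines (highest other 3150), 4978 among the 4 silenced lines (579) and 4 genes moving alike at both lung passages (0). The same held for the overlaps of M1P and L1P at 190 (138), M1P and L2P at 304 (5), and all passaged lines at 176 (5). For L1P and L2P 2 of 100 reached 395, and the other gave 2657, with M1P arrays 1 and 2 and E1KD array 1 together in place of E1KD, which points to a structure of the arrays; the next highest gave 5.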

How the results depend on the processing

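The settings without M1P arrays 1 and 2, without those and L2P array 1, with the 75th percentile as a covariate and with array weights, and the tests made under them, were chosen only after the result was seen; the others were chosen before the data were examined.

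Each number in this paragraph counts pairs of 1 setting and 1 named gene or list in 1 comparison. For named genes that passed, 1319 pairs kept direction and side of the threshold over settings other than leaving out 1 array and 60 did not pass; on leaving out 1 array these numbers were 617 and 43. Lists that passed gave 126 and 39, and 57 and 9. For genes and lists that had not passed, 50 pairs each passed in their own direction over the settings other than leaving out 1 array, 1 further gene pair passed with its direction turned, and 5 and 11 on leaving out 1 array. The cause of the differences below was not tested, apart from the number of probe sets or arrays that a setting itself changes. Signal near the floor limits folds, 3 arrays per line limit precision, and linear-scale offsets were not run because the values are log2. Under leaving out 1 array of 3 the remaining arrays share the spread of all lines, and without M1P arrays 1 and 2 the 1 array left has no spread of its own.

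With every probe set, the changed numbers were 2839 and 1417 (at least 2-fold) for E1KD with NMuMG, 8893 and 3437 for M1P with E1KD, 14081 and 5093 for L1P with M1P, and 424 at least 2-fold for L1P with E1KD. Among 5 and 4 lines they were 10475 and 8574.

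Without genes below the median mean, 281 and 163 (2-fold) changed for L1P with E1KD, 443 and 250 for L2P with E1KD, and 5 and 5 for L2P with L1P; 2 genes moved alike at both lung passages. M1P and L1P shared 118, L1P and L2P 242 and all passaged lines 107.

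With only the lines compared, 3439 genes changed for E1KD with NMuMG, 67 and 67 (2-fold) for M1P with E1KD, 1195 for L1P with E1KD, and 288 and 263 (2-fold) for L1P with M1P.

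Without M1P arrays 1 and 2, the numbers were 3463 for E1KD with NMuMG, 809 and 400 (2-fold) for M1P with E1KD, 991 for L1P with E1KD, 1351 for L2P with E1KD, 69 and 51 for L2P with L1P, and 1327 and 574 for L1P with M1P. Among 4 lines it was 1920, at both lung passages 14, and L1P and L2P shared 817.

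Without these and L2P array 1, they were 4517, 1705 and 591 (2-fold), 1405, 1718, 76 and 56, and 2490 and 792 in the same order, with 3181 among 4 lines, 23 at both lung passages, 307 shared by M1P and L1P, and 1057 by L1P and L2P.

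With the 75th percentile as a covariate, they were 2626, 384 and 204 (2-fold), 1119, 1560, 66 and 46, and 518 and 262 in the same order, with 1619 among 4 lines and 11 at both lung passages. M1P and L2P shared 191 and L1P and L2P 942.

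Array weights were 0.12 for M1P array 1, 1.84 for M1P array 2, 0.3 for M1P array 3 and 0.3 for L2P array 1. With them 4115 genes changed for E1KD with NMuMG, 1591 for L1P with E1KD, 2547 for L2P with E1KD, and 138 and 68 (2-fold) for L2P with L1P. Among 5 and 4 lines 10008 and 8371 differed, and 37 moved alike at both lung passages. M1P and L1P shared 524, M1P and L2P 697, L1P and L2P 1312 and all passaged lines 459.

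Of 186 list tests 11 passed, 1 with an estimated correlation and 29 by fry. Lifr was the only gene to change sign with a call, at -0.94 in M1P with E1KD (adjusted p = 0.0102) when its probe set with the largest variance stood for it, against 0.11 (0.606); over its alternatives the adjusted p ran from 0.0102 to 0.913.

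Leaving out 1 array gave 999 to 1245 genes for E1KD with NMuMG, 1106 to 8510 (583 to 3462 2-fold) for M1P with E1KD, 272 to 298 for L1P with E1KD, 424 to 602 for L2P with E1KD, and 2489 to 9863 (999 to 3820 2-fold) for L1P with M1P. It gave 4259 to 8910 among 5 lines, 2857 to 8208 among 4, and 3 to 7 at both lung passages. M1P and L1P shared 100 to 263, M1P and L2P 130 to 435, L1P and L2P 240 to 386 and all passaged lines 94 to 243.

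The replicate numbers of different lines share only a number. With them as a block, 2183 genes changed for E1KD with NMuMG and each count stayed within 1.5-fold. Correlations between arrays of the same number ran from -0.5 to 0.75, over 0.1 in 6, 4 and 6 of 10 pairs, and 9 of 15 arrays correlated best with their own number. With the block Pcbp1 (adjusted p = 0.0474) and Fn1 (0.0226) passed in M1P with E1KD, as did Fam3c (0.0306) and Fn1 (0.0297) in L2P with E1KD, and Bscl2 (0.071) did not pass in L2P with L1P.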

Other observations

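The chromosomes named here, and the camera tests given for them, were chosen only after the result was seen.

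Chromosome 19 genes, relative to the median of all genes, had a median of -0.35 in E1KD with NMuMG (307 expressed genes, camera adjusted p = 1.73e-06, and adjusted p = 0.849 with an estimated correlation). Against E1KD they had -0.39 in L1P and -0.41 in L2P (adjusted p = 0.165 and 0.258 with an estimated correlation). The first of 3 equal parts did not share that fall, with medians of 0.01, -0.53 and -0.48 in L1P and 0.07, -0.56 and -0.45 in L2P, against -0.58, -0.21 and -0.20 in E1KD with NMuMG. Chromosome 13 genes had a median of 0.27 in E1KD with NMuMG (adjusted p = 0.871 with an estimated correlation). In M1P with E1KD the medians were 0.49 for chromosome 7, 0.3 for chromosome 5 and -0.84 for X (each an adjusted p = 0.59 with an estimated correlation). They were 0.36, 0.25 and -0.20 without M1P arrays 1 and 2 and L2P array 1, and 0.33, 0.24 and -0.17 with the 75th percentile as a covariate. The X median came mostly from M1P arrays 1 (-1.48) and 2 (-0.71), with array 3 at -0.20. For chromosome 5 the 3 parts had medians of 0.01, 0.3 and 0.49.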
